A study of Saccharomyces cerevisiae with 47 samples.

How the data were processed

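Chromatin was assembled by salt gradient dialysis of 46 ug of plasmid library DNA with 40 ug of histone octamers, per the labels' protocols. It was incubated with a Strep-tagged factor and a remodeler where given, crosslinked with 0.05% formaldehyde for 5 min and digested with MNase. The factor was pulled down on Strep-Tactin, with 5% kept as input. Groups were taken from the sample titles, and 1 input without factor was shared by the Reb1 and Abf1 series. The labels do not say whether replicates of a group came from separate reconstitutions.

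The deposited values were 2 lists of sites with chromosome, start, end, strand and a score. Their names say that they combine in vitro ChIP, a position weight matrix and peaks. The score values were deposited by the authors with no definition and fell from the beginning of each list to its end. They were used only within a list, to rank and group sites and to compare scores by position. Whether a high score means stronger binding is not stated. The submitters' processing notes name Bowtie and the builds sacCer3 and R64, without saying what each was used for. The motif scanner, peak caller, thresholds and pooling of samples are not given in the sources used here. Whether starts count from 0 or 1 is not stated either, so positions are as deposited and uncertain by 1 bp.

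Identical rows were repeated up to 5 times. The lists held 2808 Reb1 and 3699 Abf1 rows, and each distinct chromosome, start, end and strand was counted as 1 site, 942 for Reb1 and 1365 for Abf1. This departs from the plan to count sites as deposited, because identical rows are the same site. Sites were placed by their centre against an R64 gene table of 6431 nuclear genes, 6002 of them protein-coding. Gene models were coding extents, so distances are to the start codon, and strand was read from the systematic name, which 1 gene lacked. Chromosome length was taken as the annotated span, 12053411 bp in all. The strand in the lists replaced a consensus strand for motif orientation, and tRNA and snoRNA genes were compared with protein-coding genes.

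The main tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, with the following exceptions, which were added after seeing the data. The added settings were sites listed at least 2 times, every row counted, chromosomes V to IX alone, sites below the median score, expected numbers by upstream base pairs, intergenic sites only, and genes with at least 200 bp of intergenic sequence upstream. The added tests were those of genes with both factors, of the factors against each other within a gene list, of sites moved to other promoters, of the share on chromosomes V to IX, of position between divergent or convergent genes, and those named as such in the closing section. Named genes were those downstream of the 10 highest-scoring sites of each factor (ties taken by chromosome, then start), the 10 genes with the closest Reb1 and Abf1 sites, and for each list and factor up to 4 members with the shortest distance from site to start codon, the 3 genes with most sites per factor (ties here taken by symbol), and REB1, ABF1, INO80, ISW2, CHD1 and STH1. RPO41 was named in addition, after its value was seen. The 13 lists were cytosolic and mitochondrial ribosomal proteins, proteasome, ribosome biogenesis, glycolysis, RNA polymerases, chromatin remodelers, histones, general regulatory factors, translation factors with tRNA synthetases, respiration, tRNA and snoRNA genes. Lists were taken by symbol, so a few members act elsewhere, such as RPO41 and DBP5.

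Shares have exact 95% binomial intervals. Medians and shifted lists were tested with 100000 resamples, and gene lists with Fisher's exact test and Benjamini-Hochberg adjustment over 26 tests. On chromosomes V to IX alone the histone and general regulatory factor lists had no member, so fewer tests entered that adjustment. Neighbouring sites, and genes that share a divergent promoter, are not independent, and sites are not replicates, so p-values describe these lists and not the spread between experiments. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

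The methods were tested on simulated data. In 20 simulated lists of 942 Reb1 sites with a true upstream share of 50.0%, the mean estimate was 50.0%. The upstream sites were placed inside the same 500 bp class that was then counted, so this checks the counting only. Sites placed at random passed the upstream test in 2 of 20 lists for each factor. A list of 79 genes given a weight of 4 was found in 18 of 20 simulated Reb1 lists and 19 of 20 Abf1 lists. Without an effect it passed in 2 and 0. Passing here rested on the unadjusted p-value of Fisher's exact test, without the adjustment over 26 tests applied to the real lists. These counts therefore do not give the detection rate or the false-call rate of the reported gene-list calls. For shared sites, 50 planted neighbours gave a mean excess of 48.7 and passed in 20 of 20 lists, against 1 of 20 without planted neighbours. Apart from the planted neighbours, these sites were placed at random along the chromosomes, without a preference for promoters. The simulation therefore does not show how often a preference shared by both factors would pass by itself. No genome sequence was used here, so the planned tests of motif, unlisted motif matches and flanking AT content were not run.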

Results

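The study reconstituted yeast chromatin in vitro from a plasmid library and purified histones, and asked where the DNA-binding factors Reb1 and Abf1 bound it with and without chromatin remodelers. Reb1 and Abf1 are general regulatory factors of budding yeast that bind defined sequence motifs in many promoters. The 47 samples were 24 pulldowns and 23 inputs, with at most 2 replicates per group. The pulldowns of each series included controls without factor or remodeler. Each factor was present at 50 nM in 5 kinds of reaction: alone, or with INO80, ISW2 or Chd1 at 24 nM, or with RSC at 12 nM. Fragments of 38 to 90 bp were kept for the pulldowns and of 120 to 180 bp for the inputs. The values analysed here were 1 list of motif sites per factor, deposited with the series as a whole, and the labels do not say which samples entered them. The lists carried no sample, so depth, replicate spread and remodeler effects could not be read from them, and every interval below covers counting error over sites only.

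The Reb1 list held 942 distinct sites and the Abf1 list 1365, on all 16 nuclear chromosomes of the R64 build. Merging overlapping sites left 941 Reb1 and 1312 Abf1 sites. Abf1 had 32 pairs of sites with centres up to 3 bp apart, 20 of them on opposite strands, and Reb1 had 0. Reb1 sites had a density of 78.2 per Mb and Abf1 sites of 113 per Mb. Chromosome I held 7 Reb1 sites (30.9 per Mb, 95% interval 12.4 to 63.6) but had the highest Abf1 density, with 38 sites (168 per Mb, 119 to 230). Reb1 was densest on chromosome V (58 sites, 101 per Mb, 76.4 to 130), and Abf1 was sparsest on chromosome XVI (74 sites, 78.1 per Mb, 61.3 to 98.0). Site numbers departed from chromosome length for Reb1 (chi-square goodness of fit by Monte Carlo draws, p = 0.0127) and Abf1 (p = 0.0109). The series text names chromosomes V to IX as the reconstituted DNA. Those chromosomes held 25.2% of Reb1 sites (22.4 to 28.1) and 23.7% of Abf1 sites (21.5 to 26.1), against 24.4% of the annotated length, and neither difference passed the test (exact binomial test, two-sided, p = 0.569 and p = 0.614). The other 705 Reb1 sites (74.8%) and 1041 Abf1 sites (76.3%) lay on chromosomes that this text does not name, so the shares, gene lists and genes given here cover DNA whose presence in the reactions is not given in the sources used here.

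Reb1 sites lay mostly in promoters, and Abf1 sites were divided between promoters and gene bodies. Of the Reb1 sites, 641 of 942 (68.0%, 95% interval 65.0 to 71.0) were within 500 bp upstream of a protein-coding start codon. Of the Abf1 sites, 716 of 1365 (52.5%, 49.8 to 55.1) were. This class covered 21.3% of base pairs, so both shares were above it (exact binomial test, two-sided, p = 9.53e-208 for Reb1 and p = 1.75e-140 for Abf1). The background here was all base pairs, because motif matches could not be located without a genome sequence. The shares in this section therefore do not separate where a factor bound from where its motif occurs. Intergenic DNA between divergently transcribed genes covered 8.63% of base pairs and held 36.3% of Reb1 sites (33.2 to 39.5) and 24.8% of Abf1 sites (22.6 to 27.2). That between tandem genes covered 13.4% and held 36.9% of Reb1 sites (33.9 to 40.1) and 25.4% of Abf1 sites (23.1 to 27.8). Intergenic DNA between convergent genes covered 4.20% of base pairs and held 2.23% of Reb1 sites (1.39 to 3.39; exact p = 0.00146) and 1.25% of Abf1 sites (0.727 to 1.99; p = 4.99e-10).

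The top Reb1 score of 14.3 was shared by 39 sites, of which 33 (84.6%, 69.5 to 94.1) lay within 500 bp upstream of a gene. The 10 that came earliest in chromosome order, all on chromosomes III to VII, included sites upstream of the proteasome subunit genes RPT2 (chromosome IV, 437883 to 437892) and RPN3 (chromosome V, 196784 to 196793), each 160 bp from the start codon. Others were upstream of TAF2, a TFIID subunit gene (143 bp), SNF11, a SWI/SNF subunit gene (220 bp), MOT2 (224 bp), OKP1 (138 bp), NAT2 (178 bp) and PDE1 (424 bp). The highest-scoring Abf1 site (chromosome XV, 727338 to 727353, score 16.1) lay between the divergent genes GEP3 and NOC2, 111 and 167 bp from their start codons. The divergent promoters of SET3 and GMH1 (113 and 336 bp), IRC19 and RIX7 (112 and 151 bp) and SAM37 and RNA14 (111 and 129 bp) also held top Abf1 sites, as did the promoters of PET20 (246 bp), DSN1 (169 bp) and MNN10 (224 bp). Another 2 of the 10 Abf1 sites were inside genes, FRA1 and COM2. Most genes with a site had 1, in 705 of 753 for Reb1 and 710 of 809 for Abf1. MBF1 and YER188C-A had 4 Reb1 sites each, and BUD7 was the first in alphabetical order of 8 genes with 3. YHR130C had 7 Abf1 sites, and AFG3 and PGA2 were the first of 4 genes with 4. The YHR130C sites scored at most 10.9, below the Abf1 median of 11.98. At YHR130C, AFG3 and PGA2 the nearest Abf1 site lay inside a protein-coding gene.

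Compared directly, Reb1 sites were upstream of genes more often than Abf1 sites, by 15.6 percentage points (SE 2.03; odds ratio 1.93, 95% interval 1.62 to 2.31; Fisher's exact test, two-sided, p = 6.17e-14). The intergenic shares were 75.9% for Reb1 (73.0 to 78.6) and 51.6% for Abf1 (48.9 to 54.3), a difference of 24.3 points (SE 1.94; exact p = 5.64e-33). Abf1 sites lay inside protein-coding genes in 48.2% of cases (45.5 to 50.9) and Reb1 sites in 23.8% (21.1 to 26.6), with 72.9% of base pairs in that class. Some of these sites were also upstream of another gene, so this class overlaps the upstream one. Among sites at or above each list's median score the upstream difference was 5.37 points and missed the threshold (exact p = 0.0518), while the intergenic difference was 11.9 points (p = 3.65e-06). Below the median score the upstream difference was 25.5 points (exact p = 1.02e-16), a split chosen after seeing the data.

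Upstream sites of both factors were most frequent 100 to 200 bp from the start codon. From 50 to 100 bp lay 1.38% of all Reb1 and 1.32% of all Abf1 sites, against 18.0% and 12.2% from 100 to 150 bp. Among sites within 1000 bp upstream, the median distance was 206 bp for 751 Reb1 sites (interquartile range 149 to 368) and 249 bp for 943 Abf1 sites (161 to 490). The difference was -43 bp for Reb1 minus Abf1 (bootstrap SE 10.6; permutation test, two-sided, p = 7e-05). Among sites within 500 bp the medians were 186 and 194.5 bp, and the difference of -8.5 bp (SE 7.08) did not pass the permutation test (p = 0.330).

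**Figure D1:**
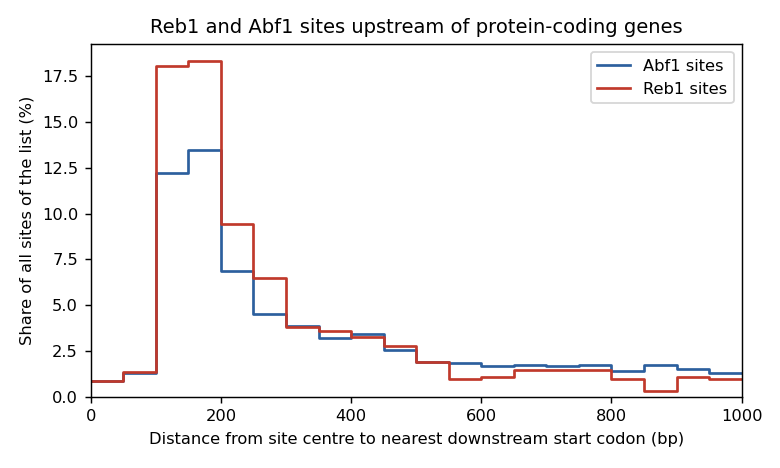
Share of all sites of each list (%, y axis) by distance from the site centre to the nearest downstream start codon (bp, x axis, bins of 50 bp), for Reb1 (red) and Abf1 (blue). Both lines peak at 150 to 200 bp, where 18.4% of Reb1 and 13.5% of Abf1 sites lay.

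Motif strand was compared with the strand of the downstream gene at sites upstream of a single gene. Reb1 sites were on the gene's strand in 210 of 472 cases (44.5%, 39.9 to 49.1; exact binomial test, two-sided, p = 0.0188), and Abf1 sites in 252 of 509 (49.5%, 45.1 to 53.9; p = 0.859). The difference between the factors did not pass Fisher's exact test (p = 0.125). Within 300 bp the Reb1 share was 46.1% and no longer passed the exact test (p = 0.114).

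Few Reb1 and Abf1 sites overlapped, and Reb1 sites lay near Abf1 sites more often than randomly shifted sites did, while the comparison with sites moved to other promoters depended on which promoters were used. Only 4 Reb1 sites overlapped an Abf1 site by at least 1 bp, against 2.38 in circularly shifted lists (permutation test, two-sided, p = 0.433). Within 200 bp of an Abf1 site lay 92 Reb1 sites (9.77%), against 38.1 in shifted lists (central 95% 26 to 52), a 2.42-fold excess (permutation p = 2e-05, the smallest the shifts can give). The excess was 1.68-fold with shifts of at most 2 kb, which keep the local density of sites (permutation p = 2e-05). Counting upstream sites alone, 62 lay within 200 bp of an Abf1 site, against 70.3 when they were moved to the same distances before randomly drawn protein-coding genes (0.882-fold, one-sided permutation p = 0.873), and against 54.0 when moved among genes with an upstream Reb1 site (1.15-fold, p = 0.0110). Both moves were added after seeing the data, the first of them after the result of the second. Closest together were the sites in the divergent promoter of MIP1, the mitochondrial DNA polymerase gene, and VMA4, a vacuolar ATPase gene, with centres 2 bp apart on chromosome XV (Reb1 from 943505, Abf1 from 943504). The divergent promoter of HEK2 and RIB1 held sites 10 bp apart, CYC1, the cytochrome c gene, 12 bp, and ARB1 and PHM8 13 bp. The divergent promoter of FRQ1 and VPS74, and that of SNF2, the SWI/SNF ATPase gene, held sites 15 bp apart.

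**Figure D2:**
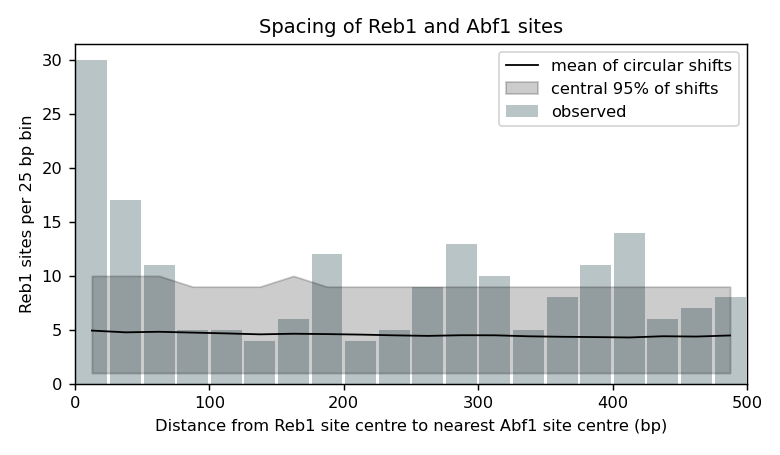
Number of Reb1 sites (y axis, bins of 25 bp) by distance to the nearest Abf1 site centre (bp, x axis). Bars are observed numbers, the line is the mean of circular shifts and the band their central 95%. The bin up to 25 bp held 30 Reb1 sites, against a mean of 4.93.

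Counted by gene, 753 of 6002 protein-coding genes had a Reb1 site within 500 bp upstream and 809 had an Abf1 site. Both were present at 81 genes, against 101 if the factors were independent (odds ratio 0.749, 0.579 to 0.957; Fisher's exact test, two-sided, p = 0.0192). This count was added after seeing the data and depended on the setting: with 1000 bp upstream the odds ratio was 1.27 (exact p = 0.00546), and with sites listed at least 2 times it was 0.957 (p = 0.788).

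Proteasome genes, and translation factor and tRNA synthetase genes, carried sites of each factor more often than other genes. Proteasome genes had an upstream Reb1 site in 13 of 34 cases (odds ratio 4.37, 2.00 to 9.19; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 26 tests, p = 0.00066) and an Abf1 site in 12 of 34 (3.54, 1.59 to 7.50; adjusted p = 0.00457). Those nearest the start codon were RPN12 and RPT4 (131 bp each), PRE6 (144 bp) and PRE4 (156 bp) for Reb1, and RPN13 (132 bp), PRE8 (138 bp), PRE7 (142 bp) and RPN11 (146 bp) for Abf1. Translation factor and tRNA synthetase genes had Reb1 sites in 13 of 44 cases (2.96, 1.41 to 5.85; exact adjusted p = 0.00704), among them VAS1 (143 bp), GCD1 (145 bp), GCD11 (160 bp) and ILS1 (174 bp). They had Abf1 sites in 17 of 44 (4.11, 2.09 to 7.85; exact adjusted p = 0.000171), among them TYS1 (129 bp), TIF35 (134 bp), FRS2 (135 bp) and GLN4 (140 bp).

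Ribosome biogenesis genes had Abf1 sites in 29 of 79 cases (odds ratio 3.82, 2.32 to 6.20; exact adjusted p = 1.26e-06), including UTP13 (121 bp), RRP8 (126 bp), RRP43 (128 bp) and RIX1 (133 bp). They had Reb1 sites in 11 of 79 (1.13, 0.536 to 2.16; exact adjusted p = 0.864), including DBP6 (115 bp), NOP6 (127 bp), RRP36 (134 bp) and DBP5 (136 bp), the last an RNA helicase gene of mRNA export. In a direct test of the factors, added after seeing the data, 9 members had Reb1 alone and 27 had Abf1 alone (exact binomial test, two-sided, p = 0.00686), which did not pass after adjustment over 11 lists (adjusted p = 0.0754). The expected share in this test was that of Reb1 among all genes with sites of 1 factor alone, not an even split. RNA polymerase genes had Abf1 sites in 11 of 32 cases (3.39, 1.47 to 7.40; exact adjusted p = 0.00704), including RPC40 (123 bp), RET1 (149 bp), RPC25 (151 bp) and RPC19 (152 bp), and also RPO41, the mitochondrial RNA polymerase gene. Their Reb1 count was 6 of 32 (exact adjusted p = 0.458), with RPB9 (129 bp), RPA14 (146 bp), RPB11 (158 bp) and RPC19 (169 bp). Genes for tRNAs had sites less often than protein-coding genes, with 8 of 275 for Reb1 (0.209, 0.0889 to 0.420) and 9 of 275 for Abf1 (0.217, 0.0978 to 0.421; exact adjusted p = 5.73e-07 for both).

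The other lists did not pass after adjustment at 500 bp with all sites. Cytosolic ribosomal protein genes had Reb1 sites in 9 of 137 cases, such as RPL11B (37 bp) and RPL15B (153 bp), and Abf1 sites in 10 of 137, such as RPS21A (137 bp) and RPS28A (156 bp; exact adjusted p = 0.0842 for both factors). Mitochondrial ribosomal protein genes had 13 of 67 for Reb1, such as MRP13 (46 bp; exact adjusted p = 0.176), and 15 of 67 for Abf1, such as MRP49 (109 bp; adjusted p = 0.0909). Chromatin remodeler genes had 8 of 30 for Reb1, such as RSC8 (115 bp) and IES4 (120 bp; exact adjusted p = 0.0909), and 5 of 30 for Abf1, such as IES2 (69 bp) and ARP8 (123 bp; adjusted p = 0.767). Respiration genes had 8 of 57 for Reb1, such as COX14 (112 bp; exact adjusted p = 0.852), and 11 of 57 for Abf1, such as COX23 (36 bp; adjusted p = 0.413). Genes for snoRNAs had 16 of 76 for Reb1 (exact adjusted p = 0.0842) and 9 of 76 for Abf1 (adjusted p = 0.978). Glycolysis genes had 2 of 16 for each factor, GLK1 and TPI1 for Reb1 and HXK2 and FBA1 for Abf1 (exact adjusted p = 1.0 for both). Histone genes had 1 of 10 for Reb1, HTZ1 (473 bp; exact adjusted p = 1.0), and 0 of 10 for Abf1 (adjusted p = 0.576). General regulatory factor genes had 1 of 6 for each factor (exact adjusted p = 0.767 for both).

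**Figure D3:**
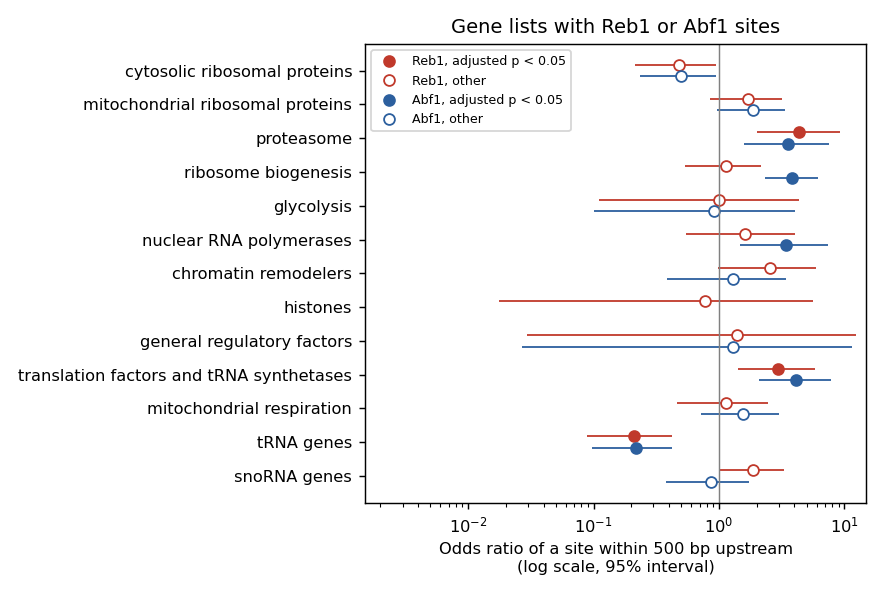
Odds ratio (x axis, log scale) of having a site within 500 bp upstream, for 13 gene lists (y axis) and both factors, Reb1 in red and Abf1 in blue. Lines are 95% intervals and filled points passed an adjusted p of 0.05, and no point is drawn for histone genes with Abf1, where 0 of 10 had a site. Proteasome genes lie at 4.37 and 3.54 and tRNA genes at 0.209 and 0.217.

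On chromosomes V to IX alone, which hold 1465 of the 6002 protein-coding genes, 0 lists passed for Reb1 and 3 for Abf1, a restriction chosen after seeing the data. Fewer genes were tested there, and 5 calls were lost. The Reb1 odds ratios of lost calls were 3.68 at proteasome genes (0.959 to 12.4; exact adjusted p = 0.0999), 3.77 at translation genes (0.802 to 15.0; adjusted p = 0.115) and 0.314 at tRNA genes (0.0827 to 0.849; adjusted p = 0.0726). Those of Abf1 were 2.05 at proteasome genes (0.364 to 7.88; exact adjusted p = 0.410), below the main 3.54, and 0.360 at tRNA genes (0.0947 to 0.976; adjusted p = 0.102). The 3 Abf1 lists that passed (exact adjusted p = 0.0434 each) were ribosome biogenesis (7 of 18, odds ratio 4.90), translation (5 of 11, 6.36) and RNA polymerases, the last resting on 3 of 4 genes (22.7, 1.81 to 1197). Other single settings ended 3 calls. At or above the median score the odds ratio of Reb1 at translation genes was 1.64 (0.503 to 4.20; exact adjusted p = 0.430), against 2.96 with all sites, and that of Abf1 at RNA polymerase genes was 2.75 (1.00 to 6.59; adjusted p = 0.0720), against 3.39. With sites listed at least 2 times, a setting added after seeing the data, the odds ratio of Abf1 at proteasome genes was 2.13 (0.781 to 5.04; exact adjusted p = 0.194), against 3.54. Single settings also gave calls absent from the main setting. With 1000 bp upstream, cytosolic ribosomal protein genes had fewer sites than other genes (exact adjusted p = 0.0394 for Reb1 and 0.0457 for Abf1), and glycolysis genes had more Abf1 sites (odds ratio 3.39, adjusted p = 0.0457). With 300 bp, mitochondrial ribosomal protein genes had more sites (exact adjusted p = 0.0268 for Reb1 and 0.0291 for Abf1). Genes for snoRNAs had more Reb1 sites at or above the median score (exact adjusted p = 0.0443) and with the nearer divergent gene only (adjusted p = 0.0311).

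Each factor had sites at its own gene. REB1 had 2 Reb1 sites upstream, the nearer 125 bp from its start codon, and no Abf1 site within 500 bp. ABF1 had 2 Abf1 sites, the nearer 169 bp from its start codon, and no Reb1 site. Of the catalytic genes of the remodelers used, CHD1 had a Reb1 site 450 bp upstream, and INO80, ISW2 and STH1, the RSC ATPase gene, had no site of either factor.

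Upstream sites had higher scores than sites inside genes that were not also upstream. In this comparison, genic sites were those inside a gene and not within 500 bp upstream of another, and upstream sites included some inside genes. The authors' score had a median of 12.6 at 641 upstream Reb1 sites and 11.9 at 187 genic ones, a difference of 0.655 (permutation test, two-sided, p = 3e-05). At 716 upstream and 558 genic Abf1 sites the medians were 12.5 and 11.5, a difference of 1.04 (permutation p = 1e-05, the smallest the resamples can give). From the lowest to the highest of 4 score groups the upstream share went from 57.7% (51.2 to 63.99) to 78.9% (73.0 to 84.1) for Reb1 and from 32.4% (27.5 to 37.7) to 72.5% (67.5 to 77.2) for Abf1.

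**Figure D4:**
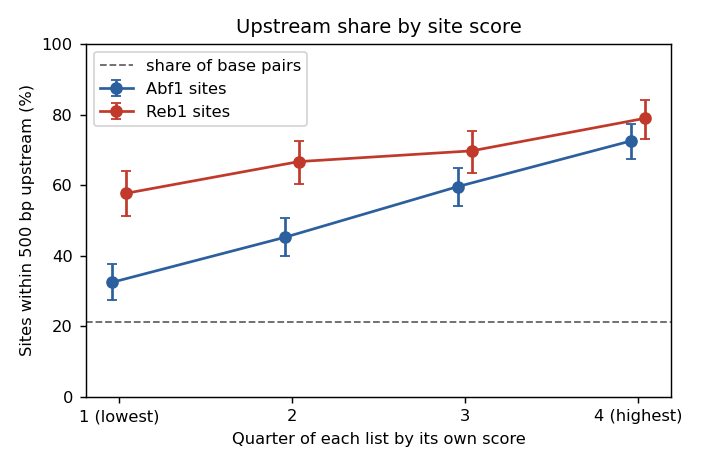
Share of sites within 500 bp upstream of a start codon (%, y axis) in 4 groups of each list by its own score (x axis), for Reb1 (red) and Abf1 (blue). Bars are exact 95% binomial intervals and the dashed line is the share of base pairs, 21.3%. The Abf1 share climbs from 32.4% to 72.5%.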

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

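The tests of chromosome ends, of the score split and of repeats against score were chosen only after the result was seen, and that of repeats at neighbouring sites after the repeats were seen but before its own result.

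Reb1 and Abf1 differed in the share of sites upstream of genes (Fisher's exact test, two-sided, p = 6.17e-14), in the intergenic share (exact p = 5.64e-33) and in distance to the start codon (permutation test, two-sided, p = 7.00e-05). Their share of sites within 20 kb of a chromosome end also differed, at 5.63% for Reb1 and 1.76% for Abf1 (Fisher's exact test, two-sided, p = 6.99e-07), with 5.31% of base pairs in these regions. The difference in upstream share was itself larger below the median score than above it, with odds ratios of 2.84 and 1.28 (Zelen's exact test of equal odds ratios, two-sided, p = 1.43e-05).

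Rows of the lists were repeated, up to 5 times for Reb1 and up to 5 times for Abf1, and the repeats entered no planned comparison. If repeats counted peaks or peak lists that cover a site, neighbouring sites would share their number. Among 35 Reb1 neighbours within 30 bp, 97.1% had equal repeats, against 20.7% after shuffling, and among 88 Abf1 neighbours 93.2% did, against 21.5%. Repeats had a low rank correlation with score across sites, which are not independent replicates (Spearman rho 0.160 for Reb1 and 0.0878 for Abf1). Because the score has no stated definition, this does not decide whether the motif scan alone gave the repeats. A candidate explanation is that each repeat is 1 kind of reaction in which a peak was called, since 5 kinds held the factor, but the labels do not say so and no biological explanation was tested.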

How the results depend on the processing

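Tests chosen only after the data were seen were all those on genes with both factors and those with sites listed at least 2 times, every row, chromosomes V to IX, sites below the median score, expected numbers by upstream base pairs, intergenic sites only, or genes with 200 bp of intergenic upstream sequence. The prediction for upstream base pairs was written before its own result. Of the main tested values, 24 under planned settings and 27 under added ones kept their direction and side of the threshold. They include the upstream share of each factor, although it was 64.2% for Reb1 and 38.7% for Abf1 below the median score, an added setting, and 71.3% and 65.9% at or above it. Another 10 counts of sites or lists under planned settings and 8 under added ones stayed within 1.5 times the main count. Among single gene lists, 85 values under planned and 82 under added settings kept direction and side, and 2 and 6 calls were lost. Another 6 calls were gained with the odds ratio on the same side of 1, all under planned settings. The odds ratio moved to the other side of 1 under 11 planned and 12 added ones. At or above the median score the difference in upstream share was 5.37 points, within 500 bp the difference in distance was -8.5 bp, and within 300 bp the Reb1 same-strand share was 46.1%, and these no longer passed. The cause was not tested. Counting every row, an added setting, gave 2808 Reb1 and 3699 Abf1 entries because identical rows repeat. On chromosomes V to IX alone, also added, the lists past the threshold numbered 0 for Reb1 and 3 for Abf1, with fewer genes tested and fewer tests in the adjustment. The odds ratio for genes with both factors turned to 1.27 with 1000 bp upstream, and no longer passed at 0.785 with the nearer divergent gene only, 0.957 with sites listed at least 2 times and 0.682 on chromosomes V to IX. The odds ratio of Abf1 at glycolysis genes, 0.917, turned to 3.39 with 1000 bp upstream and passed.

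The other turns were at lists that passed under neither the main nor that setting, and the cause was not tested. With 1000 bp upstream the odds ratio of Reb1 at glycolysis genes went from 0.996 to 2.34 and that of Abf1 at snoRNA genes from 0.862 to 1.07. With 300 bp, Reb1 at respiration genes went from 1.14 to 0.936. At or above the median score, Reb1 was at 1.83 for glycolysis, 1.42 for histone (main 0.774) and 0.963 for respiration genes, and Abf1 at 0.335 for chromatin remodelers (main 1.29). With the nearer divergent gene only, Reb1 was at 1.004 for histone genes, and Abf1 at 1.20 for glycolysis and 1.13 for snoRNA genes. With sites listed at least 2 times, glycolysis genes were at 1.20 for Reb1 and 1.17 for Abf1, and respiration genes at 0.991 for Reb1. Glycolysis genes were at 1.06 for Reb1 and 1.02 for Abf1 with intergenic sites only, and at 1.02 for Reb1 among genes with 200 bp of intergenic upstream sequence. On chromosomes V to IX, Reb1 was at 0.380 for ribosome biogenesis (main 1.13) and 0.650 for respiration genes, and Abf1 at 0.0 for mitochondrial ribosomal protein (main 1.87), 1.496 for glycolysis, 0.829 for chromatin remodeler and 1.24 for snoRNA genes.

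No paired analysis was possible because the lists carry no samples, although the labels share replicate numbers. The motif, unlisted-match and flanking AT alternatives, and the restriction to sites with the core consensus, were not run without a genome sequence.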

Other observations

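Tests of a shared sequence, of missing DNA, of chromosome ends, and of expected numbers by upstream base pairs, and the moves of sites, were chosen only after the data were seen. Of these, the prediction for upstream base pairs and that for moves within 200 bp among genes with an upstream Reb1 site were written before their results.

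Abf1 sites were sparse near chromosome ends, where 24 sites (1.76%, 1.13 to 2.60) lay within 20 kb of an end, against 5.31% of base pairs (exact binomial test, two-sided, p = 2.92e-11). Reb1 had 53 sites there (5.63%, 4.24 to 7.30; exact p = 0.662), of which 9 were upstream of a gene and 5 inside one. The longest stretch without a site of either factor was chromosome XVI from 770870 to 883670, which holds 54 protein-coding genes and was named after its value was seen.

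The neighbouring of Reb1 and Abf1 sites was weighed against the frequency of both in promoters, and the 2 ways of doing so gave different answers. Moving upstream Reb1 sites among genes with an upstream Reb1 site gave 54.0 within 200 bp of an Abf1 site, against 62 observed (one-sided permutation p = 0.0110), the only comparison of these predicted beforehand. Within 50 bp, a distance chosen after results were seen, it gave 20.3 against 36 (permutation p = 1.00e-04, the smallest the draws can give). Moving them among all protein-coding genes gave 70.3 within 200 bp (one-sided permutation p = 0.873) and 28.4 within 50 bp (p = 0.0871), so an excess over promoters in general was not shown. The comparison predicted beforehand went against similar distances as the whole account of the spacing, but the move among all protein-coding genes did not. Because the 2 disagree, they do not decide this question. The excess over random positions may still owe much to promoters. A single sequence matching both matrices is argued against, since 8.33% (2.32 to 20.0) of the 48 Reb1 sites within 50 bp overlapped the Abf1 site, and no biological explanation was tested.

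Site numbers were uneven between chromosomes. The amount of upstream sequence as the whole cause is argued against by Monte Carlo p-values of 0.0289 for Reb1 and 0.00168 for Abf1 with expected numbers set by upstream base pairs. Stretches of DNA missing from the library could lower both factors together. In 11 windows of 50000 bp without a Reb1 site, Abf1 sites numbered 0.792 of their mean elsewhere (bootstrap interval 0.444 to 1.15). Of these windows, 2 held no Abf1 site either. The 2 longest stretches without a site of either factor adjoined on chromosome XVI, 770870 to 883670 and 883671 to 942628, and were picked after being seen. Over all 232 windows the site numbers of the factors were weakly correlated (Pearson r 0.102). This explanation stays open because few windows lacked Reb1 sites, and no biological explanation was tested.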
